A study of Homo sapiens with 4 samples.

How the data were processed

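WERI-Rb1 cells were profiled on 4 arrays, 2 untreated and 2 labelled as nucleolin treated; group and replicate number come from the sample labels. Per the labels, total RNA was extracted with Trizol and labelled with Cy3. Per the file headers, the arrays (design 021827) were scanned in 1 colour and quantified with Agilent Feature Extraction 10.7.3.1 under the protocol miRNA_107_Sep09, with spatial detrending on, multiplicative detrending off and no surrogate values. The deposited scanner files give, per spot, a background-subtracted intensity, a mean intensity and a local background intensity, and per miRNA a total intensity in which miRNAs that were not detected are set to 0.1; none of these was scaled between arrays. They also hold flags of other kinds, per the file headers 0 or 1, for spots well above background, saturated or outlying and for detected miRNAs.

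The authors' deposited value table is on a log2 scale. Set against the scanner files, its differences between arrays equalled those of the log2 total intensity plus 1 constant per array, to within 0.0015, and every row was centred on a median of 0; its column medians were -0.083, -0.335, 0.907 and 0.083 for control 1, control 2, treated 1 and treated 2. Of its 961 entries, 924 matched a non-control name of the scanner files and 37 did not or were controls, and 262 tested miRNAs were matched. The origin of the constants stays unknown. This table was used only as an alternative.

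From the scanner files, the processed intensity was taken per spot. Control spots (715 per array) and spots marked as non-uniform or as population outliers (3762 over all arrays, 6.26%) were left out, and saturated spots were kept. This left 2689 probes with 4 to 16 spots each for 939 entries, 851 human and 88 viral, with 1 to 4 probes per entry. Spots of a probe and then probes of a miRNA were averaged on the linear scale; of 119 tested miRNAs with at least 2 bright probes, none had probes that disagreed in direction by over 0.5 log2. Each array was divided by its 75th percentile over the 310 probes well above background on all arrays (over 0.5 of the kept spots), because under 50% of human entries were detected on each array. Values were floored at 0.0230 of that percentile, the median over arrays of the lowest scaled signal of a bright probe, and then taken as log2, so that the floor lies at -5.45. Values at the floor have no order, and a log2 change against them understates the difference. miRNA names and probe positions (hg19) are those of the array files, and names can be old; no hg19 gene annotation was used here.

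Human miRNAs well above background on both arrays of at least 1 group were tested (268, of which 18 were at the floor on all 4 arrays, 49 on both treated arrays, and 169 on none). The treated group was compared with the control group with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjustment, threshold 0.05; 2 residual and 0.639 prior degrees of freedom). The change on a single treated array is its log2 value minus the mean of the controls. For a miRNA well above background on both arrays of 1 group and on neither of the other, the fold is a lower bound, the bright group's mean against the dim group's mean of, per array, the higher of the lowest bright probe signal and the miRNA's own signal. Fixed before the data were examined were the test, 19 lists with 273 members, of which 269 are on the array, and the rule for named miRNAs. The 17 lists with at least 3 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry. camera sets a list against the other miRNAs, so its direction can differ from the sign of a list's median; it was upward with a negative median for the retinal and neuronal, the stromal and endothelial, the passenger-strand and the other-RNA lists. With an estimated correlation, adjusted p in camera was 0.986 for every list. This form rests on at most 2 residual degrees of freedom and can hardly pass any list. A failure with it therefore does not show that correlated members explain a call. In fry, which asks whether the members of 1 list change, the smallest unadjusted p for change in either direction was 0.000366, for entries of other RNAs, followed by 0.0098 for the p53-linked list. The named miRNAs were those past the threshold or, as none passed, the 6 with the smallest p in each direction, all tested nucleolin-linked miRNAs, the 2 members with the smallest p of every other tested list, the 3 largest lower-bound folds in each direction and the 5 brightest; this gave 50. Other miRNAs named in the text, among them the members of a list quoted per array, were chosen after their values were seen.

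The procedure was tested on simulated data for 268 miRNAs in 2 against 2 arrays, 60 of them changed, in 20 runs. With the spread of the control pair (SD 0.158 log2), 97.8% of 2-fold and 100% of 4-fold changes were recovered and 3.73% of calls were false. With that of the treated pair (SD 1.08 log2), 0% of either were recovered and 100% of the calls made were false. Each spread was given to all 4 arrays, whereas in the data the controls were tight and the treated pair was wide. Neither setting therefore gives the power of the real comparison. A list shifted by 1 log2 was recovered in 100% of runs, with members that varied independently at the spread of the control pair. In the data the estimated correlation was 0.687 for the list of GC-rich entries. These runs therefore cannot show how the list test behaves when members move together.

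Alternatives were the 75th percentile over all probes, no scaling, quantile normalization, normexp background correction (offset 50), the total intensity, the brightest probe or the mean of log2 probe values per miRNA, the deposited value table, other filters on dim miRNAs, 0.5 of the floor, a variance trend, the replicate number as a block, each replicate left out, an adjusted p of 0.1, an added 2-fold limit, and, chosen after seeing the data, scaling by the labelling spike-ins and removal of a trend with probe GC content. Tables and plots were made with Python 3.11.15 and matplotlib 3.10.9.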

Results

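MicroRNA (miRNA) levels were measured in WERI-Rb1 cells, an established human retinoblastoma line, on 1-colour Agilent human miRNA arrays. There were 2 untreated control arrays and 2 arrays of cells labelled as nucleolin treated. Nucleolin is an abundant nucleolar protein that also appears on the surface of many tumour cells and takes part in the processing of some primary miRNAs, and the series title names a therapy with an aptamer, a folded oligonucleotide that binds this protein. The labels give a range of 0.5 to 20 µmol/l for the viability assay of the treated cells; the dose and the aptamer form behind the arrays are not given in the sources used here. Each array carried probes for 851 human and 88 viral entries. Of the human entries, 268 (31.5%) and 321 (37.7%) were well above background on control replicates 1 and 2, against 191 (22.4%) and 224 (26.3%) on treated replicates 1 and 2. The 75th percentile of the probes that were bright on every array was 673 and 792 intensity units on the controls, 318 on treated replicate 1 and 779 on treated replicate 2. The number of arrays limits the precision of every value.

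The treated arrays differed far more from each other than the control arrays did. On treated replicate 1, 50 of the 268 tested miRNAs lay over 2-fold above the control mean and 73 lay over 2-fold below it, whereas on treated replicate 2 only 1 lay above and 10 below, and no miRNA differed by over 2-fold between the control arrays. miR-494, a miRNA of the imprinted cluster on chromosome 14, was 53.6-fold above the control mean on treated replicate 1 and 2.02-fold above it on treated replicate 2. miR-30b was 14.2-fold below the control mean on treated replicate 1 and 1.27-fold below on treated replicate 2, and for miR-16 these values were 5.54-fold and 1.20-fold. miR-923, an entry whose sequence lies in ribosomal RNA, was the brightest signal on all 4 arrays and made up 23.9% and 18.7% of the summed human signal of the controls, at least 47.7% of that of treated replicate 1 and at least 27.4% of that of treated replicate 2, where 16 and 8 of its 16 spots were saturated.

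Across the tested miRNAs, Pearson's r was 0.996 between the controls, 0.819 between the treated arrays, 0.989 and 0.990 between treated replicate 2 and the controls, and 0.804 and 0.777 between treated replicate 1 and the controls; miRNAs are not independent replicates. The median absolute log2 difference was 0.12 between the controls and 0.86 between the treated arrays. Over the 169 miRNAs above the floor on every array, the change from the control mean had an SD of 1.72 on treated replicate 1 and 0.35 on treated replicate 2, and the difference between the controls had an SD of 0.19. RNA spike-ins added before labelling had 45.2% and 54.7% of their mean control signal on treated replicate 1, while the spike-ins added at hybridisation had 101% and 104% there. All arrays lay on 1 slide with 1 scan date, and the controls and the treated samples held separate positions on it, so position and group cannot be told apart.

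**Figure D1:**
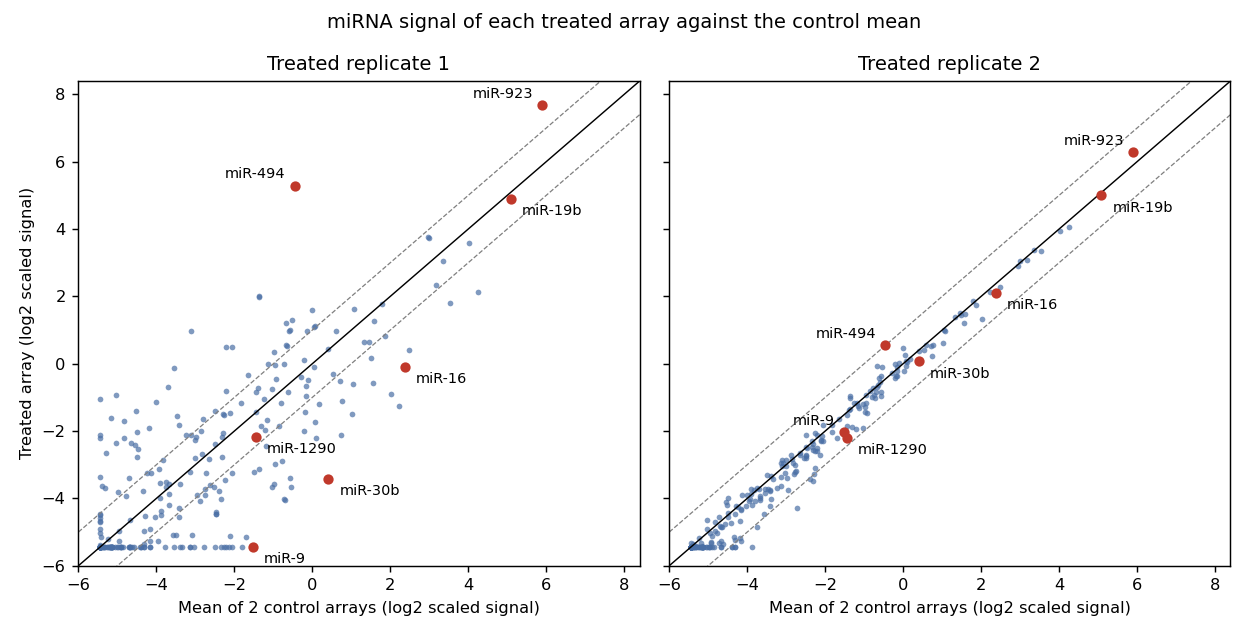
Scaled log2 signal of the 268 tested miRNAs on treated replicate 1 (left) and treated replicate 2 (right) against the mean of the 2 control arrays, 1 point per miRNA. The solid line marks equal signal, dashed lines a 2-fold difference and red points named miRNAs; the points scatter widely on the left, with 50 miRNAs over 2-fold above and 73 over 2-fold below the control mean, and lie close to the line on the right.

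The comparison of treated with untreated cells asked which miRNAs changed after the treatment. Among miRNAs above the floor on all arrays, miR-1290, miR-197 and miR-574-3p had the smallest p and were lower on both treated arrays by almost the same amount. miR-1290 had a log2 change of -0.75 (SE 0.06, n = 2 against 2 arrays; limma adjusted p = 0.330), with -0.72 on treated replicate 1 and -0.77 on treated replicate 2. miR-197 had -0.55 (SE 0.08; limma adjusted p = 0.374), with -0.54 and -0.56, and miR-574-3p had -0.75 (SE 0.11; limma adjusted p = 0.374), with -0.76 and -0.74. None of the 268 tested miRNAs passed an adjusted p of 0.05 in limma. An unadjusted limma p under 0.05 was reached by 21, all of them lower in the treated group. Of these 21, 6 were at the floor on both treated arrays and only 8 were above the floor on all 4 arrays. Every tested miRNA was well above background on both controls, and none entered through the treated arrays alone, so the filter itself favours falls. When the arrays were scaled by the 75th percentile of all probes, miR-1290, miR-197 and miR-574-3p had positive changes of 0.70, 0.90 and 0.70. This scaling shifted the median change from -0.16 to 0.70. With it, 4 miRNAs passed and 67 had an unadjusted limma p under 0.05, all higher. On the treated arrays this percentile was 1.34 and 2.40 intensity units, below 1 SD of their negative controls (2.67 and 2.85). It moved the change of every miRNA above the floor by the same log2 amount.

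The count depended on which treated array was included. In a limma fit without treated replicate 2, in which treated replicate 1 is assumed to vary like the controls, 146 miRNAs passed, 71 higher and 75 lower, whereas without treated replicate 1 none passed and 36 had an unadjusted p under 0.05. The smallest 2-sided p that an exact permutation of 2 against 2 arrays can reach is 0.333. As the labels do not say that replicates were separate cultures, p-values measure only the spread between these arrays, which may be technical.

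Among miRNAs with a positive change, the smallest p belonged to miR-93, a member of the growth-promoting miR-106b-25 cluster, with a log2 change of 0.26 (SE 0.09; limma adjusted p = 0.554) and values of 0.32 and 0.21 on treated replicates 1 and 2. It was followed by miR-886-3p, an entry whose sequence lies in a vault RNA, with 1.25 (1.89 and 0.61), miR-1268 with 1.04 (1.60 and 0.48), miR-181c with 0.49 (0.76 and 0.22), miR-663 with 1.23 (1.96 and 0.49) and miR-1915 with 1.13 (1.83 and 0.43). None of these passed, and for miR-93 and miR-181c the change was -0.29 and -0.06 with no scaling between arrays. Among the lower miRNAs of smallest p, miR-1271, miR-383 and miR-192 had floored values on both treated arrays, at log2 changes of -1.05, -0.55 and -0.77, so that their treated spread was 0 by construction. With normexp background correction these changes were 0.53, 0.55 and 0.52. Over the 169 miRNAs above the floor on all arrays, 28 had both treated arrays above both controls and 60 had both below. With interchangeable arrays 16.7% would be expected in each direction. Together 52.1% were seen, against 33.3%, but miRNAs are not independent. The counts of 28 and 60 became 124 and 0 under the all-probe percentile and 94 and 30 with normexp, so that the balance depended on the scaling.

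**Figure D2:**
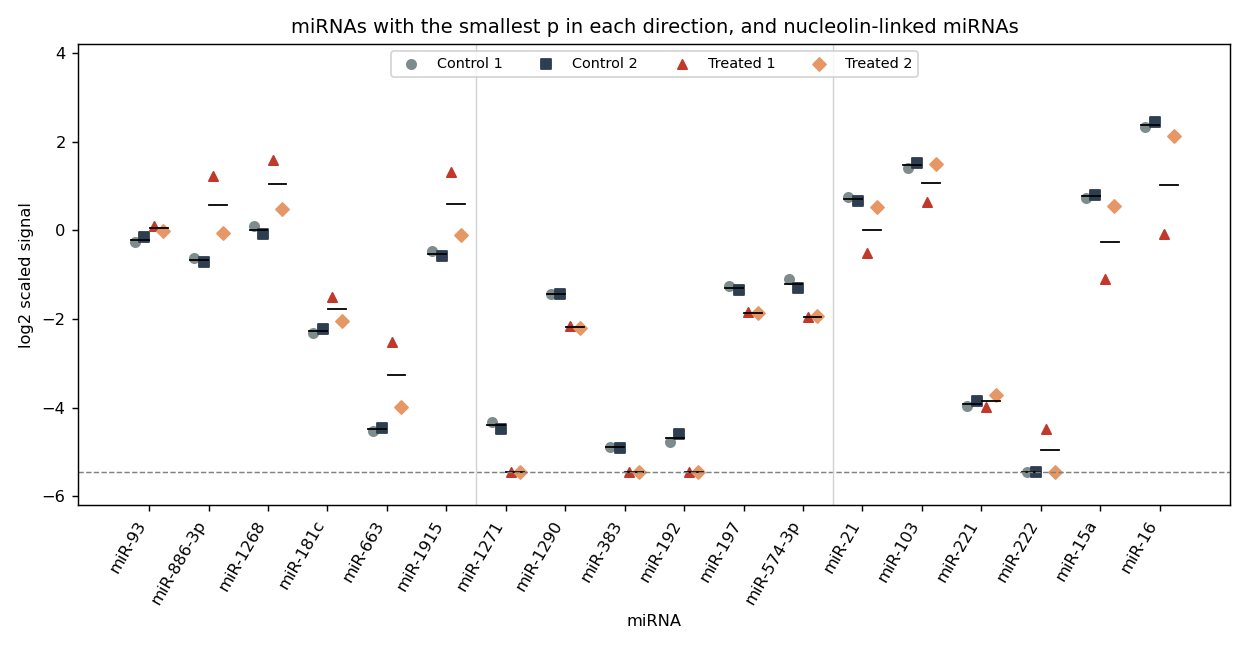
Scaled log2 signal on each of the 4 arrays (symbols) and the mean of each pair (black bars) for the 6 positive and 6 negative changes of smallest p and for the 6 nucleolin-linked miRNAs; the dashed line is the floor at -5.45. The treated pair nearly coincides for miR-1290, miR-197 and miR-574-3p, while for miR-16 treated replicate 1 lies at -0.09 and treated replicate 2 at 2.12, next to the controls at 2.33 and 2.44.

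The 6 miRNAs whose maturation has been linked to nucleolin in other cells gave 2 positive and 4 negative changes, none past the threshold. miR-21, a widely expressed oncogenic miRNA, had a log2 change of -0.70 (SE 0.45; limma adjusted p = 0.554), made of -1.22 on treated replicate 1 and -0.19 on treated replicate 2. The clustered miR-15a and miR-16, known repressors of cell-cycle genes, had -1.04 (-1.86 and -0.21) and -1.37 (-2.47 and -0.27). miR-103 had -0.40, with -0.83 on treated replicate 1 and 0.04 on treated replicate 2. miR-221 had 0.06 (SE 0.14), and miR-222 was at the floor on 3 arrays. The median of the list was -0.55, with -1.02 on treated replicate 1 and -0.09 on treated replicate 2 (limma camera, adjusted p = 0.985), and 0 members passed when adjusted over the list alone. With the all-probe percentile the median was 0.63 (limma camera, adjusted p = 0.971). With normexp it was -0.57 and the list passed, as lower than the other miRNAs (limma camera, adjusted p = 0.0178, but adjusted p = 0.672 with an estimated correlation). With a trend with probe GC content removed the median was 0.13.

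The let-7 family, repressors of growth and stem-cell genes, was negative in all 9 tested members, with a median of -1.46 (limma camera, adjusted p = 0.0860). On treated replicate 1 the median was -2.51, with let-7g at -3.45 and let-7a at -2.51 but let-7b at 0.26; on treated replicate 2 all 9 were lower, with a median of -0.50. miR-98, the member of smallest p, had -1.19 (limma adjusted p = 0.374), with -1.28, at the floor, and -1.11, and let-7c had -0.37. All 6 members of the miR-15/16 family were negative, with a median of -1.27 (limma camera, adjusted p = 0.699), and miR-15b had -2.12 on treated replicate 1 and -0.35 on treated replicate 2. Under the all-probe percentile the let-7 median was -0.01 and that of the miR-15/16 family 0.16. In the fit without treated replicate 2, 6 of 9 let-7 and 5 of 6 miR-15/16 members passed as lower, and without treated replicate 1 none passed. Both lists passed in limma camera, as lower than the other miRNAs, with normexp (medians -0.24 and -0.51; adjusted p = 0.00590 and 0.0178) and with no filter (medians -1.46 and -1.23; adjusted p = 2.39e-06 and 0.0281). With an estimated correlation neither passed (limma camera, adjusted p = 0.672 for each with normexp and 0.754 for each with no filter). With the GC trend removed their medians were -0.64 and -0.74.

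The miR-17-92 cluster and its paralogs, which drive proliferation in retinoblastoma and other tumours, held several of the brightest miRNAs of these cells and went both ways, with 4 positive and 7 negative changes and a median of -0.25 (limma camera, adjusted p = 0.985). miR-19b and miR-19a had small log2 changes of -0.15 and -0.25, whereas miR-20a of the same cluster had -1.15, with -2.11 on treated replicate 1 and -0.19 on treated replicate 2, and miR-92a had 0.82 and -0.04. The median was 1.19 under the all-probe percentile and -0.44 with normexp, where the list passed as lower than the other miRNAs (limma camera, adjusted p = 5.17e-06, but adjusted p = 0.672 with an estimated correlation). It was 0.09 with the GC trend removed. The passenger strands gave 2 positive and 2 negative changes (adjusted p = 0.958 in limma camera), among them miR-19b-1* at -0.80 and miR-20a* at -1.42; their median of -0.29 was 0.44 under the all-probe percentile. Of 10 miRNAs induced by or matured with p53, 9 were negative, with a median of -0.50 (limma camera, adjusted p = 0.0860). The median was -0.82 on treated replicate 1 and -0.16 on treated replicate 2. But their best-ranked members, miR-192 and miR-194, were at the floor on both treated arrays. The median was 0.57 under the all-probe percentile and 0.51 with normexp. With normexp the dim miR-192 and miR-194 had 0.52 and 0.56, values that mainly reflect its offset. This list passed as lower in limma camera with no filter (median -0.40, adjusted p = 2.39e-06), with the detection flag as filter (-0.50, 0.0263), with a variance trend (-0.50, 0.0196) and without control replicate 1 (-0.61, 0.0405). With an estimated correlation, adjusted p in limma camera was 0.754 with no filter, 0.966 with the detection flag and 0.911 with a variance trend. With the GC trend removed the median was -0.18.

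Of the 14 tested miRNAs of photoreceptors and neurons, 6 had positive and 8 negative changes, with a median of -0.28 (limma camera, adjusted p = 0.773). The photoreceptor cluster miR-183, miR-96 and miR-182 had -1.81, -3.49 and -1.77 on treated replicate 1 and -0.22, -0.10 and 0.03 on treated replicate 2. The neuronal miR-9, at the floor on treated replicate 1, had -3.93 and -0.50, and miR-7 had -2.91 and -0.69, while miR-181a had 1.59 and 0.05 and miR-124 had 0.73 and 0.05. In the fit without treated replicate 2, 6 of the 14 rose and 6 fell, and without treated replicate 1 none passed. The median turned to 0.75 under the all-probe percentile and to 0.19 with normexp. Of 5 tested miRNAs named as abundant in an earlier survey of retinoblastoma, 4 had positive changes, with a median of 0.66 (limma camera, adjusted p = 0.149). The median was 1.31 on treated replicate 1 and 0.0065 on treated replicate 2. The list included miR-494 at 3.38 (SE 2.08, limma adjusted p = 0.554), whose probe reads positions 101496026 to 101496039 of chromosome 14 on the hg19 build, and let-7e at -1.46.

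Of 17 lists tested, only that of GC-rich entries, named beforehand as often bright with partly degraded RNA, passed in limma camera at the preset correlation. In fry the unadjusted p of this list was 0.589 for a shared direction and 0.362 for change in either direction. It had 24 positive and 4 negative changes among 30 tested members and a median of 0.96 (limma camera, adjusted p = 2.87e-05), but adjusted p = 0.986 with an estimated correlation. The shift lay on treated replicate 1, where 25 members were higher, with a median of 1.94 that exceeded 100% of 10000 random lists matched on mean level. On treated replicate 2 the median was -0.05, with 12 members higher and 16 lower, above 92.9% of random lists. Matching on level leaves out probe GC content, which went with the change on treated replicate 1 (Spearman 0.616), and the correlation of members (0.687). These shares are therefore no test of the list. Without treated replicate 1 the median was -0.05 (limma camera, adjusted p = 0.396), and without treated replicate 2 it was 1.94, with 21 of 30 members past the threshold. With the GC trend removed the median was 0.42 (limma camera, adjusted p = 0.384) and no list passed; among the other lists, the median then was -0.05 for photoreceptor and neuronal, -0.01 for miR-29, -0.08 for hypoxia and 0.11 for stromal and endothelial miRNAs. miR-1275 had 4.07 on treated replicate 1 and 0.24 on treated replicate 2, and miR-1202 had 3.36 and 0.35. miR-766 went the other way, with -0.95 and -0.80 (limma adjusted p = 0.450). No member passed on its own or when adjusted over the list alone.

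**Figure D3:**
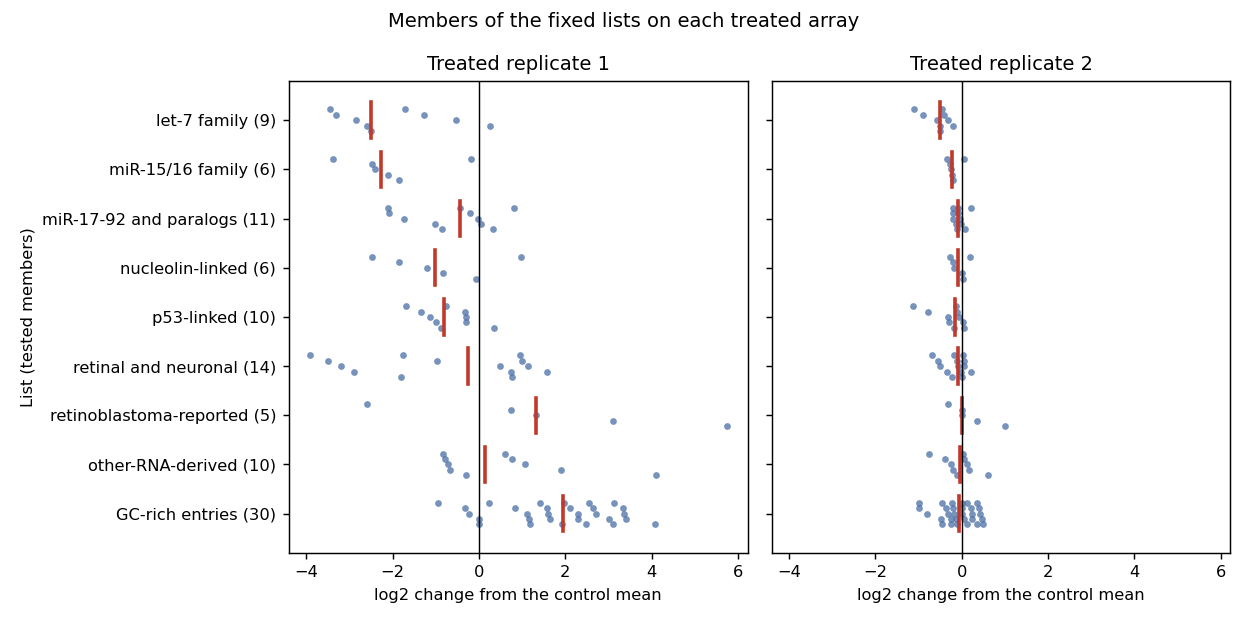
Log2 change from the control mean of each tested member of 9 lists (points) on treated replicate 1 (left) and treated replicate 2 (right), with the list median as a red bar and the number of tested members in parentheses. Medians range from -2.51 (let-7 family) to 1.94 (GC-rich entries) on treated replicate 1 and from -0.50 to 0.01 on treated replicate 2; under scaling by the 75th percentile of all probes, the medians other than that of let-7 are positive.

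Entries that lie in tRNA, vault RNA, snRNA or rRNA gave 5 positive and 5 negative changes, with a median of -0.02, a mean of 0.22 and adjusted p = 0.895 in limma camera. In fry the unadjusted p for change in either direction was 0.000366, the smallest of the tested lists. Unlike those of camera, the fry p-values were not adjusted over the lists, so the threshold was not applied to them. miR-1290 was the single member that passed when adjusted over the list alone. miR-1826 had 4.10 on treated replicate 1 and 0.12 on treated replicate 2, and miR-720 had -0.31 and 0.03. The miR-30 family split, with miR-30b at -3.83 and miR-30c, at the floor, at -2.32 on treated replicate 1 but miR-30a and miR-30d at 1.10 and 1.07 there. Its list median was 0.33 (limma camera, adjusted p = 0.773), with 0.65 on treated replicate 1 and 0.0014 on treated replicate 2. The 3 tested miR-29 members had a median of -0.60 (adjusted p = 0.958 in limma camera), with miR-29b at -2.11 and 0.06 on treated replicates 1 and 2. The median of this list was -1.04 on treated replicate 1 and 0.06 on treated replicate 2. Hypoxia and stress miRNAs had 2 positive and 7 negative changes and a median of -0.29 (limma camera, adjusted p = 0.895), with miR-23a at -2.03 and -0.22 and miR-373, floored in both treated arrays, at -0.29. Under the all-probe percentile the medians of the miR-29 and the hypoxia lists were 0.81 and 0.83; the hypoxia list passed with normexp (median -0.16; limma camera, adjusted p = 0.0191, but adjusted p = 0.672 with an estimated correlation), and with no scaling that of the miR-30 family was -0.22. In the imprinted chromosome 14 cluster, 4 of 46 members were tested (median 0.48; limma camera, adjusted p = 0.788), with miR-134 at 2.11 and 0.42 and the dim miR-487b at -0.32. In the primate chromosome 19 cluster, 3 were tested (median 0, limma camera adjusted p = 0.958), with miR-520d-3p at -0.61 and, at the floor, -1.57.

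Markers of other cell types were sparse. Of 9 blood and immune markers only miR-486-5p was tested, with 1.76 on treated replicate 1 and 0.04 on treated replicate 2, and of the 2 pigment epithelium miRNAs only miR-204, at the floor on both treated arrays. Stromal and endothelial markers had 1 positive and 3 negative changes (median -0.28; limma camera, adjusted p = 0.985), and a median of 0.30 under the all-probe percentile, with miR-126 at -2.96 and -0.21 and miR-143 at -0.87 and -0.18, both at the floor on treated replicate 1. Of the epithelial markers, miR-141 had 1.31 and 0.17 and the dim miR-203 had -0.53 and -0.21 (list median 0; limma camera, adjusted p = 0.895). No member of these lists passed, alone or adjusted over its list alone.

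Of the tested miRNAs, 167 were well above background on all 4 arrays, 57 on all but treated replicate 1, 7 on all but treated replicate 2 and 37 on the controls only; none was well above background on both treated arrays and neither control. Of those 37, a lower bound on the fold exceeded 1 for 3. miR-1306 was at least 1.30-fold, miR-34b, a p53-induced miRNA, at least 1.28-fold and miR-206 at least 1.01-fold higher in the controls (limma adjusted p = 0.450, 0.450 and 0.554). Of the 88 viral entries, a background in these cells, 9 and 10 were well above background on the controls, 7 on treated replicate 1 and 5 on treated replicate 2.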

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

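All tests of explanations in this part were chosen after the results were seen.

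Probes for viral miRNAs took no part in the comparison of the groups, and 5 of them were over 2-fold brighter on treated replicate 1 than on the brighter control. The log2 difference was 5.24 for hiv1-miR-H1 and 3.34 for hsv1-miR-H1, which were at the floor on both controls, 5.00 for ebv-miR-BART19-3p, which was at the floor on 1 control, 2.65 for kshv-miR-K12-3 and 2.02 for ebv-miR-BART13. On treated replicate 2 none of these probes exceeded the brighter control by over 2-fold, the differences being 0, 0, 0.03, 0.25 and -0.41. The values say what the probes bound, not that viral RNA was present.

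The pattern behind these values is that treated replicate 1 stood apart from the other 3 arrays. A weaker labelling reaction on that array alone would lower all signals, and the labelling spike-ins were indeed at 45.2% and 54.7% of the controls; yet, of 167 miRNAs well above background on all arrays, 20 were over 2-fold higher than both controls before any scaling, beside 85 over 2-fold lower, which argues against it as the whole cause. A trend with probe GC content, which explained 35.1% of the variance of the change on treated replicate 1, left an SD of 1.39 once removed, 7.20 times the SD of 0.19 between the controls, so it is at most a part. A treatment response of like size in both treated samples would give similar changes on both treated arrays. Yet the slopes of treated replicate 2 on treated replicate 1, each against its own control, were 0.12 and 0.03 over 169 miRNAs. Pearson's r for the same comparisons was 0.54 and 0.16. As treated replicate 1 varied far more, small slopes do not exclude a shared pattern of smaller size on treated replicate 2. A response that differed in size between the treated samples was not tested and stays open beside the quality of the RNA or of the hybridisation.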

How the results depend on the processing

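Scaling by the labelling spike-ins and removal of a GC trend were chosen after seeing the data; the other alternatives were planned. The count of 0 changed miRNAs (21 at an unadjusted limma p under 0.05) held under all alternatives except 3. It was 4 with the 75th percentile over all probes, all higher (miR-1280, miR-145, miR-181c and miR-484). It was 18 with the deposited value table, all lower, and all 18 sat at the placeholder for undetected miRNAs on both treated arrays, so their treated SD of 0.58 log2 came only from the constants per array. It ranged from 0 to 146 when 1 array was left out, with 146 without treated replicate 2; a lone array was then assumed to vary like the other group. The number of lists past the threshold, 1, became 0 with the all-probe percentile, with an estimated correlation and with the GC trend removed, 6 with normexp (added: let-7, miR-15/16, miR-17-92, nucleolin-linked, hypoxia), 4 with no filter (added: let-7, miR-15/16, p53), 2 with the detection flag or a variance trend and 0 to 2 with 1 array left out (added: p53). All lists added were lower than the other miRNAs. With an estimated correlation taken in the same setting, no camera call of a list held in any setting. For the GC-rich list with normexp the estimated correlation was 0.0099, near the preset 0.01. Its adjusted p in limma camera was still 0.637, against 8.26e-06 at the preset value. These losses therefore rest at least in part on the few degrees of freedom. They do not decide whether members that moved together explain the calls. The list of GC-rich entries had its median of 0.96 under an estimated correlation (adjusted p 0.986), 2.20 with the all-probe percentile (adjusted p 0.370) and 0.42 with the GC trend removed (adjusted p 0.384), and from -0.053 (without treated replicate 1, adjusted p 0.396) to 1.94 with 1 array left out; over its other alternatives the camera p stayed under the threshold. The replicate block left 0 miRNAs and 1 list past the threshold, with 10 unadjusted p under 0.05. Deviations of same-numbered arrays correlated at 0.70 over 169 miRNAs, but with 2 pairs the numbers are not taken to pair the arrays. A slide block was not run, as there was 1 slide. The correlation of the treated arrays was 0.819, and 0.812 unscaled or 0.803 with the total intensity.

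Of 982 values of the 50 named miRNAs under alternatives, 875 kept their direction and side of the threshold, 36 passed it and 71 changed sign; 12 miRNAs never did. Of 337 list values, 322 kept both, the direction being that against other miRNAs. The all-probe percentile lay close to background, at 6.28 and 8.21 intensity units on the controls and 1.34 and 2.40 on the treated arrays, and so raised treated values. On the treated arrays it was below 1 SD of the negative controls, 2.67 and 2.85. A new divisor moves the log2 change of every miRNA above the floor by the same amount. This scaling thus turned signs above the floor by 1 shared shift. It gave log2 changes of 0.041 for miR-1271, 0.70 for miR-1290, 0.23 for miR-192, 0.90 for miR-197, 0.70 for miR-574-3p, 0.75 for miR-21, 1.05 for miR-103, 0.41 for miR-15a, 0.079 for miR-16, 0.31 for miR-520d-3p, 0.41 for miR-203, 0.58 for miR-766, 0.32 for miR-23a, 0.23 for miR-98, 1.08 for let-7c, 0.22 for miR-15b, 1.30 for miR-19b, 0.65 for miR-19b-1*, 0.032 for miR-20a*, 0.81 for miR-29a, 0.42 for miR-29b, 0.0097 for miR-30c, 0.16 for miR-194, 0.60 for miR-143, 0.21 for miR-1306, 1.19 for miR-19a, 0.30 for miR-20a and 1.31 for miR-720. Normexp moved the median change to 0.55, and all 40 miRNAs of unadjusted p under 0.05 were then higher. It gave 0.53 for miR-1271, 0.55 for miR-383, 0.52 for miR-192, 0.69 for miR-520d-3p, 0.55 for miR-487b, 0.52 for miR-203, 0.54 for miR-766, miR-373 and miR-98 each, 0.72 for let-7c, 0.45 for miR-19b-1*, 0.68 for miR-29a, 0.47 for miR-30c, 0.56 for miR-194, 0.58 for miR-143, 0.17 for miR-126, 0.65 for miR-1306, 0.51 for miR-34b and 0.57 for miR-206. Most of these miRNAs are dim. The offset of 50 was added to every spot before the arrays were divided by their percentiles. With the processed intensity, the percentile of the shared bright probes was 318 on treated replicate 1, against 673, 792 and 779 elsewhere. The same offset therefore counts for more on treated replicate 1. Named miRNAs floored on both treated arrays had main changes from -1.13 to -0.29, yet took 0.51 to 0.57 with normexp. Their normexp sign thus mainly reflects the offset and the percentiles. For the other miRNAs, how much this explains was not tested. With no scaling (median change -0.48; 6 of 26 unadjusted p under 0.05 higher), miR-93 was at -0.29, miR-181c at -0.064, miR-221 at -0.49 and miR-498 at -0.019. Quantile normalization (median -0.11; 5 of 14 higher) gave -0.0049 for miR-498. The total intensity (median -0.56; 35 unadjusted p under 0.05, all lower) gave -0.24 for miR-221 and -0.37 for miR-498, and the brightest probe -0.026 for miR-221. The deposited table gave -0.008 for miR-221, -0.14 for miR-498, 0.017 for miR-19b and 0.026 for miR-720. Removing the GC trend gave 0.037 for miR-21, 0.22 for miR-103, 0.041 for miR-487b, 0.32 for miR-203, 0.072 for miR-373, 0.31 for let-7c, 0.59 for miR-19b and 0.61 for miR-19a. With 1 array left out, changes ranged from -0.83 to 0.036 for miR-103, from -2.11 to 0.060 for miR-29b, from -0.31 to 0.034 for miR-720 and from -0.077 to 0.19 for miR-221. Apart from the all-probe divisor and the normexp offset, the causes of these sign changes were not tested. Signal over background limits the dim miRNAs most: 49 of the 268 tested were at the floor on both treated arrays.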

Other observations

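The arms of 1 precursor, matched by name, went apart on treated replicate 1 in some pairs and together in others. In 4 of 41 tested pairs both arms differed by over 2-fold from the control mean there, 1 in opposite directions and 3 both lower. The first was miR-424, with a log2 change of -3.39, and miR-424* with 3.33, against -0.25 and 0.12 on treated replicate 2. The others were miR-9 and miR-9* at -3.93 and -3.19, miR-20a and miR-20a* at -2.11 and -2.65, and miR-455-5p and miR-455-3p at -1.10 and -3.31. This tally was chosen after the values were seen.

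On treated replicate 2 taken alone, 11 of the 268 tested miRNAs differed by over 2-fold from the control mean, and none of these passed in the limma fit without treated replicate 1. miR-494 was the only higher one, at 1.01. The lower ones included miR-520d-3p at -1.57, at the floor, and miR-595 at -1.55. They also included miR-432, of the same chromosome 14 cluster as miR-494, at -1.17, and miR-744* at -1.03. On treated replicate 1 these had -0.61, -0.52, 0.15 and -1.39 in that order. miR-1306, miR-34b, miR-631 and miR-1271 were also among the lower ones and at the floor on treated replicate 2.

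The tests of explanations that follow were chosen after the results were seen. The control arrays differed along the same axis as the treated arrays. Across 169 miRNAs, control 1 minus control 2 correlated with treated 1 minus treated 2 at r = 0.70 (bootstrap 95% interval 0.618 to 0.782 over 2000 draws of miRNAs, which are not independent), and at 0.631 after removal of a GC trend. The differences share no array. As the controls were both untreated, a difference between RNA extracts or hybridisations that is independent of treatment may underlie this axis. Partly degraded RNA is a candidate explanation of that kind: the list of GC-rich entries, fixed beforehand as often bright with it, had a median of 0.24 over control 1 minus control 2, with 27 of 30 members higher, and of 1.77 over treated 1 minus treated 2, with 25 higher. This would also follow from any other condition that favours GC-rich probes, and RNA quality was not measured here.

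A smaller pattern, in the main scaling, was a negative change of like size on both treated arrays. Among 157 miRNAs well above background and above the floor, 7 differed by over 0.5 log2 between the groups with under 0.5 within each pair, all lower in the treated pair: miR-1281, miR-1290, miR-197, miR-574-3p, miR-744*, miR-766 and miR-885-5p. The direction depended on the scaling: over the same 157, the all-probe percentile gave 0 lower and 32 higher, normexp 0 and 36, and no scaling 7 and 5. The total intensity gave 8 and 0, removal of the GC trend 5 and 1, quantile normalization 5 and 3, and spike-in scaling 4 and 3. The 7 miRNAs all kept a negative change in these settings, except with the all-probe percentile (0 of 7) and normexp (3 of 7). The all-probe percentile adds 1 shared shift, and the normexp offset weighs most on dim miRNAs. In the main scaling the other splits of the 4 arrays into pairs gave at most 1 such miRNA, but 3 splits are too few for a share under 0.05. Those other splits also put 1 control in each pair. As the controls differed by an SD of only 0.19, a low count there was nearly fixed beforehand. Position on the slide, which goes with the group, cannot be told apart from the treatment. Of 5 viral entries bright on all arrays, 1, ebv-miR-BART12, was also lower by over 0.5 log2 on both treated arrays. Its changes of -0.80 and -1.72 were not of like size. A response to the treatment stays open, as a hypothesis that these arrays do not settle, and its direction with it.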
